A study of Mus musculus with 63 samples.

How the data were processed

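RNA was measured in 63 libraries of sorted dorsal cortex cells of Ski knock-out mouse embryos, in 19 groups of 2 to 6 libraries. Cells were dissociated with papain, GFP-positive cells were collected by fluorescence-activated sorting, RNA was taken with TRIzol and libraries were made with the TruSeq RNA v2 kit and sequenced as single 50 base reads on an Illumina HiSeq, per the labels. Reads were quantified with kallisto 0.43.0, with the builds GRCm38.p2 and mm10 named, per the submitters' processing notes. The deposited values are TPM per gene, 1 value for each of 23078 genes and 63 libraries, not log2 values per the labels. The column sums, which are near 1000000 TPM in each library, were checked against that unit. No read counts are part of the sources used here, so no depth per library, no counting error and no detection floor could be given, and precision rests on the spread between libraries alone.

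All values here were computed from the deposited TPM as log2(TPM + 1). Genes with at least 1 TPM in at least 3 libraries were tested (15231 of 23078). Above 0 TPM were 16823 to 21890 genes per library. Symbols were matched for 22361 gene IDs. One linear model with a mean for each of the 19 groups was fitted to all 63 libraries with limma 3.58.1 in R 4.3.3, with moderated variances following a trend on mean level. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 change of at least 1 in size. Cell types were compared as the mean of their differences on shared days. Slopes on day were fitted through the group means and are given as the change over the whole span. Curvature is the fitted quadratic at mid-course minus the mean of its ends. Differences between slopes were tested as contrasts of the same model. Embryonic day 15.5 is the middle of E12.5 to E18.5 and carries no weight in slopes over those days.

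The comparisons, gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Named are the 5 genes with the largest change in each direction among those with a mean of at least 10 TPM in a group (3 for slope differences and curvature), up to 3 genes of smallest adjusted p and the largest opposite one for each list described, and a fixed set of genes in every comparison. Some genes that this rule names are not reported here. The fixed set has Ski, Hes5, Pax6, Eomes, Neurog2, Tubb3, Neurod6, Bcl11b, Hmga2, Gfap, Olig2, Mki67, Xist and Ddx3y. Hes5 and Eomes (Tbr2) are the genes whose reporters were used for sorting.

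There are 30 gene lists. They cover radial glia, basal progenitors, neuronal differentiation, deep-layer and upper-layer neurons, synapse, S phase, G2 and M phase, the Notch pathway, TGF-beta and BMP response, SKI partners, Wnt response, early temporal progenitors, astrocytes, the oligodendrocyte lineage, early neuroepithelium and patterning, interneurons and Cajal-Retzius cells. They also cover endothelium and pericytes, microglia and macrophages, erythroid cells, meninges and fibroblasts, choroid plexus, ependyma and cilia, immediate early and dissociation genes, hypoxia and glycolysis, p53 response and apoptosis and cholesterol synthesis. Lists with at least 5 tested genes, 28 in all, were tested with camera in limma at a preset correlation between genes of 0.01 and again with the correlation estimated from the data, adjusted over the 28 lists of a comparison. The Y-linked list (4 genes) and the X-inactivation list (2 genes) are too small and served to check the sex label. Counts of called genes in a list are given with p adjusted over all genes and, where they differ, over the list alone.

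The alternatives were pseudocounts of 0.1 and 5, no low-value filter, a mean of at least 5 TPM, and quantile and median-of-ratios scaling. Further ones were library weights, the mean log2(TPM + 1) of the Y-linked genes as a covariate, only the libraries of a contrast, and a block on replicate number. Slopes were also replaced by the last day minus the first, and each library was left out in turn. Added later were leaving out E18.5, only E12.5 to E14.5 for NSC and BP, leaving out NSC of E17.5 or of E12.5, leaving out libraries beyond 1.5 standard deviations on the first axis of variation within groups, and the rank correlation with transcript length in each library as a covariate. A count was taken as moved where it changed by more than 1.5 times. Transcript length and GC content come from the GENCODE vM21 annotation, which may not be the release behind the deposited values.

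The tests were checked on simulated data of the same layout, with 200 of 15231 genes changed. Their noise was independent between genes and libraries, whereas in the deposited data 29.4% of the variance within groups lies on 1 axis. The false calls below therefore hold for independent noise only. At a true log2 change of 1.5, between 84% and 100% of changed genes were called in the 9 comparisons, and at 3 between 99% and 100%, with 0 to 4 false calls. For each comparison, 100 splits of the libraries, the real one included, were compared by their number of called genes. The splits shuffled cell type within each day, or days where a comparison has 1 cell type. Within groups of 4 to 10 libraries a library far from the others was sought with Dixon's test for 18 genes in 5 groups, the largest of 6 libraries. Knock-out and wild type were not compared, as no wild type library is in the series. All 63 libraries were used.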

Results

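The data cover 63 RNA libraries from sorted dorsal cortex cells of Ski knock-out C57Bl/6 mouse embryos, in 19 groups of cell type and embryonic day. Neural stem cells (NSC) were sorted by Hes5::GFP at E11.5 to E18.5 (26 libraries). Basal progenitors (BP) at E12.5 to E18.5 (24 libraries) and newborn neurons (NBN) at E15.5 to E18.5 (13 libraries) were sorted by Tbr2::GFP. How BP and NBN were told apart within that sort is not given in the sources used here. No wild type library is in the series, so every result below describes Ski knock-out cells and none describes an effect of Ski. Values are in TPM, given as mean ± standard deviation, and changes are log2 changes of TPM ± standard error. For a single day the deviation is between the libraries of a group. In comparisons of cell types TPM values are means over the shared days, with the deviation between day means and not between libraries.

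Cell type and day order the libraries. The library closest to each one belonged to the same cell type in 63 of 63 cases and to the same group in 41 of 63. The first principal component holds 40.2% of the variance and the first 2 together 52.7%. Libraries of a group correlated with each other at a mean r of 0.958 to 0.996. Nothing in the labels says that replicates are separate embryos, so p-values here measure the spread between samples only.

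**Figure D1:**
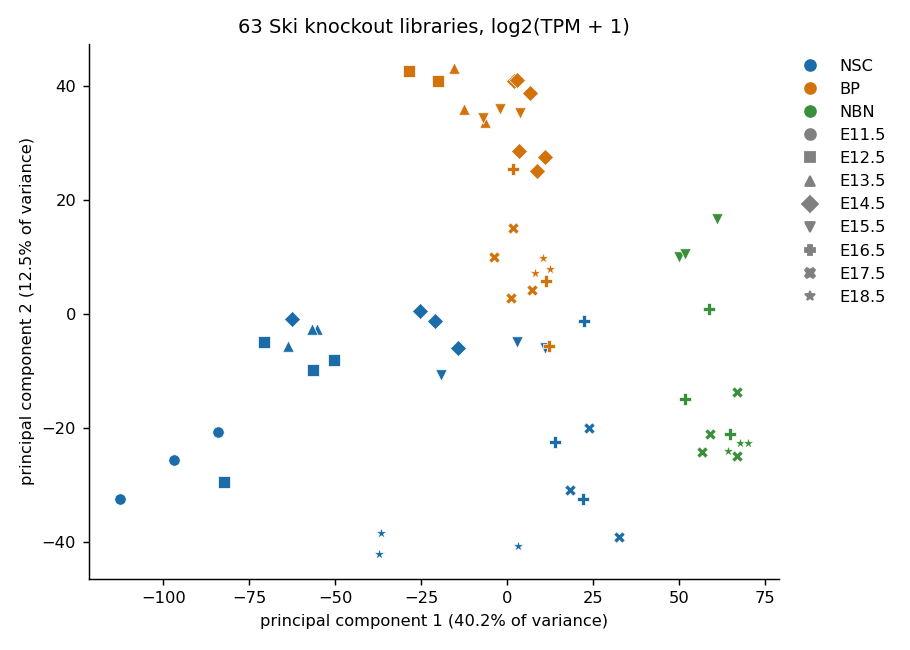
Principal components 1 and 2 of log2(TPM + 1) for 63 libraries. Each point is 1 library, with cell type and embryonic day marked.

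Ski itself, a co-repressor of TGF-beta signalling, has transcript signal in every group. Its mean TPM ran from 25.2 ± 2.14 at E11.5 (n = 3) to 42.7 ± 5.14 at E18.5 (n = 3) in NSC. In BP it ran from 17.6 ± 0.343 (n = 2) to 32.3 ± 1.47 (n = 3), and in NBN it was 43.6 ± 4.8 at E15.5 (n = 3) and 42.3 ± 1.29 at E18.5 (n = 3). NSC exceeded BP by 0.53 ± 0.06 (adjusted p = 2.68e-10), on each of the 7 shared days, and NBN exceeded BP by 0.57 ± 0.08 (adjusted p = 2.26e-08), on each of 4 days, both short of the 2-fold needed for a call. Ski passed in none of the 9 comparisons. The deleted part of the gene is not stated, and a single TPM per gene cannot show whether an exon is missing.

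Sex transcripts do not match the label, which is female for every library. At 10 TPM or more, Xist, the RNA that silences 1 X chromosome, is present in 26 libraries and the sum of 4 Y-linked genes in 39. Xist alone is present in 24 libraries, the Y-linked sum alone in 37, both in 2 and neither in 0. Xist and the Y-linked Ddx3y passed in none of the 9 comparisons.

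NSC and BP were compared on 7 days (23 and 24 libraries). Hes5, a Notch effector whose reporter was used for sorting NSC, had 102 ± 42.4 TPM in NSC and 3.71 ± 0.787 in BP (4.23 ± 0.17, adjusted p = 5.03e-26), which is no finding between these groups. After it, the largest NSC excess is in the interneuron transcription factors Dlx1 (74.7 and 2.47 TPM, 4.16 ± 0.22, adjusted p = 2.5e-21) and Dlx2 (3.95 ± 0.21, adjusted p = 6.55e-21), the secreted matrix protein gene Cyr61 (3.59 ± 0.20, adjusted p = 1.37e-20) and the interneuron factor Dlx5 (3.53 ± 0.20, adjusted p = 1.19e-20). The largest BP excess is in Calb2, which encodes calretinin (-1.73 ± 0.17, adjusted p = 1e-11), Nhlh1 (-1.69 ± 0.13, adjusted p = 1.79e-15), Nr2f2 (-1.65 ± 0.28, adjusted p = 3.2e-06), Trp73, a Cajal-Retzius cell gene (-1.64 ± 0.16, adjusted p = 1.83e-12), and the hormone gene Gcg (-1.54 ± 0.12, adjusted p = 8.3e-15). Each of these 10 genes has 1 direction on 7 of 7 days, and Gcg is not called with a pseudocount of 5 (-0.99). In all, 390 of 15231 genes were higher in NSC and 71 higher in BP.

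Glial and stem cell lists were higher in NSC. Of 22 radial glia genes, 18 were higher in NSC and 0 lower, with 4 not called (adjusted p = 2.23e-22, and adjusted p = 0.0314 with an estimated correlation), among them the glutamate transporter Slc1a3 (2.78 ± 0.10, adjusted p = 6.25e-27) and Ttyh1 (2.27 ± 0.09). The astrocyte list had 12 of 25 up and 0 down (adjusted p = 2.99e-10, and adjusted p = 0.0314 with an estimated correlation), including Mlc1 (3.42 ± 0.11) and Aldh1l1 (2.15 ± 0.11). The Wnt response list had 6 of 20 up and 0 down (adjusted p = 2.29e-05, and adjusted p = 0.0339 with an estimated correlation), with the ligand Wnt7a at 2.28 ± 0.08. In the Notch list 9 of 19 genes were up and 0 down (adjusted p = 1.56e-05, and adjusted p = 0.0648 with an estimated correlation), with the receptor Notch3 at 2.66 ± 0.09 and the fringe enzyme Lfng at 3.22 ± 0.12. The oligodendrocyte list had 6 of 17 up and 0 down (adjusted p = 1.7e-06, and adjusted p = 0.0616 with an estimated correlation), with Olig1 at 2.34 ± 0.15 and Sox8 at 2.28 ± 0.11. Interneuron genes were up in 14 of 18 cases and down in 0 (adjusted p = 4.66e-14, and adjusted p = 0.0616 with an estimated correlation), among them the Dlx genes given above. Their mean log2(TPM + 1) differed between NSC libraries of 1 day, with 4.52 ± 0.99 at E12.5 and 4.09 ± 1.05 at E14.5 (n = 4 each). At E15.5 it was 3.17 ± 0.12 (n = 3). The source of these transcripts was not tested.

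Fewer lists were higher in BP. The Cajal-Retzius list had 0 genes up and 8 of 13 down in NSC (adjusted p = 1.36e-07, and adjusted p = 0.0616 with an estimated correlation). The basal progenitor list had 0 of 20 up, 3 down and 17 not called (adjusted p = 1.94e-06, and adjusted p = 0.184 with an estimated correlation). Those 3 are Nhlh1, Neurod4 (-1.19 ± 0.13, adjusted p = 2.25e-10) and Mfap4 (-1.06 ± 0.10, adjusted p = 3.76e-13). As lists, 2 more were higher in BP with few calls. Neuronal differentiation had 1 of 24 up and 1 down (adjusted p = 0.000143, and adjusted p = 0.4 with an estimated correlation). Synapse had 1 of 20 up and 1 down (adjusted p = 0.0267, and adjusted p = 0.609 with an estimated correlation). In the TGF-beta and BMP list, the pathway that Ski restrains, 4 of 20 genes were up and 1 down (adjusted p = 0.00226, and adjusted p = 0.178 with an estimated correlation). Its members Id3 (2.42 ± 0.18, adjusted p = 2.39e-16) and Id4 (1.86 ± 0.12), both inhibitors of differentiation factors, were higher in NSC and the cycle inhibitor Cdkn1a was lower (-1.14 ± 0.13, adjusted p = 4.45e-10). Without NSC of E12.5, Cdkn1a (-0.98) and Mfap4 (-0.99) are not called, nor is Mfap4 without NSC of E17.5 (-0.98) or on E12.5 to E14.5 alone (-0.82). With a pseudocount of 5, Cdkn1a (-0.92) and Neurod4 (-0.91) are not called. The list of SKI partners had 2 of 19 up and 0 down (adjusted p = 0.902), with the TGF-beta signal transducer Smad3 at 2.06 ± 0.07 (adjusted p = 1.27e-27). S phase genes had 3 of 22 up and 0 down (adjusted p = 6.92e-10, and adjusted p = 0.184 with an estimated correlation). The G2 and M list, higher in NSC, had 0 of 22 up and 0 down (adjusted p = 0.00108, and adjusted p = 0.609 with an estimated correlation). Microglia genes had 0 of 15 up and 0 down (adjusted p = 0.0438, and adjusted p = 0.709 with an estimated correlation). Adjusting over each list alone left every count of this comparison as it was.

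Among the genes followed throughout, the growth regulator Hmga2 was 1.5 ± 0.14 (adjusted p = 3e-13) and the glial factor Olig2 2.10 ± 0.17 (adjusted p = 5.67e-15) higher in NSC, each on 7 of 7 days. Not called were Pax6 (0.67 ± 0.11), Eomes (-0.87 ± 0.16), whose reporter was used for sorting BP, Neurog2 (-0.37 ± 0.11), Tubb3 (-0.29 ± 0.09), Neurod6 (-0.63 ± 0.20), Bcl11b (-0.39 ± 0.16), Gfap (0.37 ± 0.10) and Mki67 (0.29 ± 0.21). Mef2c (1.12 ± 0.19, adjusted p = 3.55e-06), a factor of maturing neurons, was called higher in NSC although only 4 of 7 days show that direction. It is not called without E18.5 (0.93) or NSC of E17.5 (0.67), and on E12.5 to E14.5 it is higher in BP (-1.24). On those days alone Pax6 (1.52), Bcl11b (-1.01) and Neurod6 (-1.20) are called. A pseudocount of 0.1 gave 740 genes higher in NSC and 157 in BP and a pseudocount of 5 gave 170 and 25. E12.5 to E14.5 alone gave 681 and 243.

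NBN and BP were compared on 4 days (13 libraries each). The largest NBN excess is in the adaptor Sla (336 ± 44.6 and 12.8 ± 4.3 TPM, 4.68 ± 0.22, adjusted p = 3.64e-23), the transcription factor Mef2c (4.54 ± 0.25, adjusted p = 8.23e-21), the guanylate cyclase subunit Gucy1a3 (4.48 ± 0.21, adjusted p = 9.14e-24), the neurotensin receptor Ntsr1 (4.36 ± 0.19, adjusted p = 2.39e-24) and neuropeptide Y, Npy (4.32 ± 0.27, adjusted p = 5.16e-19). The largest BP excess is in the matrix gene Mfap4 (15.8 ± 6.09 and 356 ± 21.3 TPM in NBN and BP, -4.52 ± 0.13, adjusted p = 7.41e-32), Nhlh1 (-4.40 ± 0.17, adjusted p = 2.34e-26), Tac2 (-3.95 ± 0.14, adjusted p = 1.67e-28), the somatostatin receptor Sstr2 (-3.60 ± 0.18, adjusted p = 1.81e-22) and Eomes (-4.21 ± 0.21, adjusted p = 1.4e-22), whose reporter served to sort both. Each of these 10 genes has 1 direction on 4 of 4 days. In all, 876 of 15231 genes were higher in NBN and 776 higher in BP.

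Progenitor and division genes were lower in NBN. Of 20 basal progenitor genes 0 were higher in NBN and 16 lower (adjusted p = 3.39e-14, and adjusted p = 0.113 with an estimated correlation), among them the Notch modifier Mfng (-3.54 ± 0.12) and Neurod1 (-2.38 ± 0.16). The G2 and M list had 0 of 22 up and 21 down (adjusted p = 1.53e-13, and adjusted p = 0.394 with an estimated correlation), with the ubiquitin enzyme Ube2c at -2.26 ± 0.12 and the spindle factor Tpx2 at -2.29 ± 0.12. In the S phase list 0 of 22 were up and 10 down (adjusted p = 1.65e-08, and adjusted p = 0.42 with an estimated correlation), with the helicase subunit Mcm2 at -1.77 ± 0.11. Calls in neuronal lists are mostly higher in NBN. Deep-layer genes had 6 of 14 up and 0 down (adjusted p = 0.000656, and adjusted p = 0.42 with an estimated correlation), including Ldb2 (3.69 ± 0.19), Hs3st4 (3.41 ± 0.19) and Nfe2l3 (2.29 ± 0.16). Upper-layer genes had 6 of 15 up and 2 down (adjusted p = 0.258). The synapse list had 7 of 20 up and 2 down (adjusted p = 0.000167, and adjusted p = 0.452 with an estimated correlation), with Camk2a at 1.64 ± 0.14 and, among those lower, the vesicular glutamate transporter Slc17a6 at -2.01 ± 0.17. Camk2a is not called with a pseudocount of 5 (0.93). In the neuronal differentiation list 10 of 24 were up and 3 down (adjusted p = 0.0112, and adjusted p = 0.864 with an estimated correlation), with the neurofilament gene Nefl at 3.32 ± 0.28.

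Microglia genes were also higher in NBN, in 11 of 15 cases with 0 lower (adjusted p = 5.23e-06, and adjusted p = 0.452 with an estimated correlation). They include the complement gene C1qa (11.4 ± 9.09 and 0.786 ± 0.683 TPM, 2.22 ± 0.28, adjusted p = 2.57e-09) and the macrophage receptor Mrc1 (1.66 ± 0.19). The cholesterol synthesis list had 1 of 18 up and 0 down (adjusted p = 3.88e-05, and adjusted p = 0.42 with an estimated correlation), the gene being Hmgcs1 (1.04 ± 0.10, adjusted p = 3.79e-13). Hmgcs1 is not called without BP E16.5 replicate 2 (0.998), NBN E16.5 replicate 1 (0.98) or E18.5 (0.87), or with the transcript length covariate (0.83). Mrc1 is 1.05 without E18.5 and not called with a pseudocount of 5 (0.72). The p53 list had 2 of 14 up and 1 down (adjusted p = 0.703). Adjusting over each list alone left every count as it was except for erythroid genes, with 2 of 10 up over all genes and 0 over the list.

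Of the genes followed throughout, the progenitor factors Pax6 (-2.23 ± 0.15, adjusted p = 5.53e-18) and Neurog2 (-2.50 ± 0.15, adjusted p = 4.86e-20) and the division marker Mki67 (-2.38 ± 0.28, adjusted p = 3.45e-10) were lower in NBN, all on 4 of 4 days. Not called were Hes5 (0.06 ± 0.22), Tubb3 (0.73 ± 0.12), Neurod6 (0.38 ± 0.27), Bcl11b (0.53 ± 0.21), Hmga2 (-0.03 ± 0.18), Gfap (-0.87 ± 0.14) and Olig2 (0.74 ± 0.22). A pseudocount of 0.1 gave 1317 genes higher in NBN and a pseudocount of 5 gave 470, with 400 higher in BP.

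NBN and NSC were compared on the same 4 days (13 and 12 libraries). NBN were higher in Hs3st4, a heparan sulfate enzyme of deep-layer neurons (54.8 ± 36.7 and 10.2 ± 7.26 TPM, 2.30 ± 0.20, adjusted p = 2.68e-14), reelin, Reln (2.01 ± 0.21, adjusted p = 1.22e-11), the neurexin ligand Nxph3 (1.97 ± 0.19, adjusted p = 9.49e-13), the dynein subunit Dync1i1 (1.96 ± 0.21, adjusted p = 3.89e-11) and Ndnf (1.93 ± 0.16, adjusted p = 1.67e-14). NSC were higher in Tac2 (-3.81 ± 0.14, adjusted p = 8.84e-27), Mfap4 (-3.28 ± 0.13, adjusted p = 1.05e-25) and Dlx1 (-3.06 ± 0.29, adjusted p = 1.74e-12). The sort genes Hes5 (-3.90 ± 0.22, adjusted p = 4.26e-20) and Eomes (-3.36 ± 0.21, adjusted p = 1.32e-18) were both higher in NSC. For all 10 genes the direction held on 4 of 4 days, with Reln at 1.27 without E18.5. In all, 388 of 15231 genes were higher in NBN and 930 higher in NSC, a share of 29.4% up, which is 42% with quantile scaling.

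Stem cell, cycle and glial lists were lower in NBN. The radial glia list had 0 of 22 up and 21 down (adjusted p = 8.48e-18, and adjusted p = 0.0619 with an estimated correlation), with Sox2 at -2.84 ± 0.14 and Vim at -2.30 ± 0.12. In the G2 and M list all 22 were down (adjusted p = 4.52e-17, and adjusted p = 0.104 with an estimated correlation), with Ccnb2 at -2.39 ± 0.12 and Cdc20 at -2.53 ± 0.13. The Notch list had 1 of 19 up and 12 down (adjusted p = 1.18e-07, and adjusted p = 0.0619 with an estimated correlation), with the receptor Notch1 at -2.69 ± 0.12. Astrocyte genes had 0 of 25 up and 13 down (adjusted p = 4.48e-07, and adjusted p = 0.0868 with an estimated correlation), oligodendrocyte genes 0 of 17 up and 8 down (adjusted p = 1.47e-05, and adjusted p = 0.105 with an estimated correlation), and interneuron genes 1 of 18 up and 13 down (adjusted p = 1.47e-05, and adjusted p = 0.288 with an estimated correlation). Neuronal differentiation genes had 10 of 24 up and 1 down (adjusted p = 0.000267, and adjusted p = 0.409 with an estimated correlation), with the growth cone gene Gap43 at 1.29 ± 0.17 (0.95 and not called without E18.5). Deep-layer genes had 6 of 14 up and 1 down (adjusted p = 1.47e-05, and adjusted p = 0.132 with an estimated correlation) and Cajal-Retzius genes 6 of 13 up and 1 down (adjusted p = 0.000334, and adjusted p = 0.199 with an estimated correlation). Immediate early and dissociation genes had 0 of 19 up and 6 down (adjusted p = 0.0848), with Btg2 at -1.65 ± 0.12. Erythroid genes had 4 of 10 up and 0 down (adjusted p = 0.0744), with the globin Hbb-bs at 1.65 ± 0.56. Over the list alone the 1 choroid plexus gene called up is not called and every other count is the same.

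Of the genes followed throughout, Pax6 (-2.26 ± 0.15, adjusted p = 1.1e-17), Neurog2 (-1.92 ± 0.15, adjusted p = 1.54e-15), Mki67 (-2.48 ± 0.29, adjusted p = 2.74e-10), Gfap (-1.50 ± 0.14, adjusted p = 5.35e-13) and Olig2 (-1.40 ± 0.22, adjusted p = 5.67e-07) were lower in NBN, on 4 of 4 days each. Not called were Tubb3 (0.67 ± 0.13), Neurod6 (0.58 ± 0.27), Bcl11b (0.45 ± 0.21) and Hmga2 (-0.77 ± 0.18). A pseudocount of 0.1 gave 731 genes up and 1419 down, a pseudocount of 5 gave 149 and 456, and leaving out E18.5 gave 252 up. Without E18.5, Gfap (-0.86) and Olig2 (-0.75) are not called. With a pseudocount of 5 Gfap is not called (-0.90), and with 0.1 Hmga2 is (-1.31).

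Over the course of NSC from E11.5 to E18.5 (26 libraries), the matrix gene Tnc, made by late radial glia and astrocytes, rose from 0.33 ± 0.178 to 442 ± 104 TPM (n = 3 each, 8.26 ± 0.29, adjusted p = 7.33e-28). Hmga2, which keeps stem cells young, fell from 365 ± 171 to 2.12 ± 0.666 (-7.54 ± 0.28, adjusted p = 3.49e-27). Also rising most were Sla (7.36 ± 0.35, adjusted p = 2.18e-23), the kinase subunit Camk2b (6.08 ± 0.35, adjusted p = 3.22e-20), the stress gene Ndrg1 (5.97 ± 0.36, adjusted p = 2.17e-19) and the adult globin Hbb-bs (6.00 ± 0.85, adjusted p = 2.86e-08). Hbb-bs is 5.26 without NSC E17.5 replicate 1. That library holds 9456 TPM of globins, against 267.2 and 231.7 in the rest of its group. Falling most were also the retinoic acid carrier Crabp2 (-7.66 ± 0.28, adjusted p = 3.8e-27), the embryonic globin Hbb-y (-5.98 ± 0.80, adjusted p = 7.66e-09), Ebf2 (-5.58 ± 0.27, adjusted p = 5.79e-23) and Fndc3c1 (-5.19 ± 0.15, adjusted p = 1.04e-30). Of 15231 genes, 2254 rose and 1244 fell, a share of 64.4% rising, which is 53.8% with quantile scaling.

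Cell cycle and early progenitor lists have falling slopes in NSC. S phase genes fell in 20 of 22 cases and rose in 0 (adjusted p = 1.18e-13, and adjusted p = 0.134 with an estimated correlation), with Ccne1 at -2.53 ± 0.17 and Fen1 at -2.0 ± 0.15. G2 and M genes fell in 22 of 22 (adjusted p = 1.61e-09, and adjusted p = 0.246 with an estimated correlation), with the survivin gene Birc5 at -2.16 ± 0.18 and the kinase Plk1 at -1.96 ± 0.18. For the last minus the first day Plk1 is -0.91 and not called. The G2 and M list turns back at the end, with a mean log2(TPM + 1) of 6.71 ± 0.37 at E11.5, 4.33 ± 0.21 at E17.5 and 6.01 ± 0.45 at E18.5 (n = 3 each). The early temporal progenitor list had 0 of 18 up and 14 down (adjusted p = 5.52e-11, and adjusted p = 0.0209 with an estimated correlation), with the cyclin Ccnd1 at -3.77 ± 0.19. Early neuroepithelium genes had 1 of 18 up and 11 down (adjusted p = 2.39e-05, and adjusted p = 0.079 with an estimated correlation), and Wnt response genes 1 of 20 up and 11 down (adjusted p = 8.26e-05, and adjusted p = 0.0677 with an estimated correlation), with the ligand Wnt8b at -4.59 ± 0.24 and the effector Lef1 at -3.12 ± 0.16. Hypoxia and glycolysis genes had 1 of 17 up and 12 down (adjusted p = 2.41e-05, and adjusted p = 0.346 with an estimated correlation), with Hk2 at -2.75 ± 0.19 and Pkm at -1.53 ± 0.13. Radial glia genes had 5 of 22 up and 12 down (adjusted p = 0.0322, and adjusted p = 0.601 with an estimated correlation). The mean of that list was 6.89 ± 0.17 at E11.5, 5.62 ± 0.40 at E17.5 and 7.33 ± 0.44 at E18.5. It does not pass with quantile scaling. Cajal-Retzius genes had 0 of 13 up and 8 down (adjusted p = 0.000415, and adjusted p = 0.246 with an estimated correlation). The p53 list had 1 of 14 up and 1 down (adjusted p = 0.181).

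Glial lists rose in NSC, and so did some neuronal ones. Neurons carried in the NSC sort, taken up below for the bend, may add to the neuronal rises. Their part in these slopes was not tested. Astrocyte genes rose in 20 of 25 cases and fell in 2 (adjusted p = 5.94e-08, and adjusted p = 0.0677 with an estimated correlation), with the GABA transporter Slc6a11 at 4.46 ± 0.18 and the adhesion protein Hepacam at 4.04 ± 0.16. Over the days to E17.5 these 2 are 2.98 and 2.02. Oligodendrocyte genes rose in 8 of 17 and fell in 1 (adjusted p = 0.0339, and adjusted p = 0.422 with an estimated correlation). Upper-layer genes rose in 12 of 15 and fell in 0 (adjusted p = 2.64e-06, and adjusted p = 0.079 with an estimated correlation), including Mdga1 (2.23 ± 0.14, adjusted p = 5.61e-19) and Dok5 (4.17 ± 0.19). Neuronal differentiation genes rose in 17 of 24 and fell in 0 (adjusted p = 2.41e-05, and adjusted p = 0.369 with an estimated correlation), with Bhlhe22 at 3.91 ± 0.25 and Mapt at 4.22 ± 0.33. Synapse genes rose in 17 of 20 and fell in 1 (adjusted p = 5.99e-07, and adjusted p = 0.184 with an estimated correlation), with Dlg2 at 4.26 ± 0.27. Deep-layer genes rose in 4 of 14 and fell in 1 (adjusted p = 0.531). Interneuron genes rose in 4 of 18 and fell in 4 (adjusted p = 0.916). Microglia genes rose in 12 of 15 and fell in 0 (adjusted p = 0.0172, and adjusted p = 0.595 with an estimated correlation). Without NSC E17.5 replicate 1 they rose in 9 and fell in 1 (adjusted p = 0.0398). The oligodendrocyte counts are then 7 and 2 (adjusted p = 0.0432). Erythroid genes had 4 of 10 up and 3 down (adjusted p = 0.685), meninges genes 6 of 13 up and 1 down (adjusted p = 0.412) and choroid plexus genes 1 of 9 up and 2 down (adjusted p = 0.612). Endothelial genes had 5 of 14 up and 0 down (adjusted p = 0.0627) and immediate early genes 7 of 19 up and 1 down (adjusted p = 0.592). Adjusting over each list alone left every count as it was.

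Of the genes followed throughout, Neurod6 (3.98 ± 0.42, adjusted p = 1e-11), Gfap (4.42 ± 0.21, adjusted p = 5.46e-23) and Olig2 (1.04 ± 0.34, adjusted p = 0.00668) rose and Hes5 (-1.36 ± 0.34, adjusted p = 0.000483), Pax6 (-1.30 ± 0.23, adjusted p = 2.96e-06) and Mki67 (-1.43 ± 0.43, adjusted p = 0.00355) fell. Not called were Eomes (0.80 ± 0.32), Neurog2 (-0.10 ± 0.23), Tubb3 (0.66 ± 0.19) and Bcl11b (0.26 ± 0.33). Over the days to E17.5 Gfap is 2.55, Hes5 -2.10, Mki67 -2.84 and Pax6 -2.05. Bcl11b (1.00) and Tubb3 (1.27) are then called rising, and Olig2 turns to a fall (-1.17). For the last minus the first day, Hes5 (-0.26, adjusted p = 0.665), Pax6 (-0.40, adjusted p = 0.283) and Mki67 (-0.09, adjusted p = 0.916) are not called and Eomes is (1.25), as it is with library weights (1.16). Without NSC of E17.5, Hes5 (-0.80), Mki67 (-1.03, adjusted p = 0.0594) and Pax6 (-0.86) are not called and Eomes is (1.31). Olig2 is 1.80 without NSC of E12.5 and not called without any 1 of 6 libraries (0.81 to 0.98, lowest without NSC E12.5 replicate 3). Nor is it called with a pseudocount of 5, median-of-ratios scaling, library weights, the libraries of the contrast alone, far libraries left out or the transcript length covariate (0.84 to 1.04). Eomes is called without NSC E12.5 replicate 3 (1.01) or NSC E18.5 replicate 1 (1.07).

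In the lists of pathways, Notch genes had 2 of 19 up and 7 down in NSC (adjusted p = 0.000576, and adjusted p = 0.184 with an estimated correlation), with the ligand Dll1 at -2.75 ± 0.13. The basal progenitor list had 2 of 20 up and 8 down (adjusted p = 0.0198, and adjusted p = 0.557 with an estimated correlation), with Neurog1 at -3.95 ± 0.22. It does not pass with quantile scaling. TGF-beta and BMP genes had 6 of 20 up and 4 down (adjusted p = 0.773), with Id2 at 2.93 ± 0.14. SKI partners had 1 of 19 up and 3 down (adjusted p = 0.0908), with Smad3 at -2.29 ± 0.15 and the deacetylase Hdac1 at -1.58 ± 0.10. A pseudocount of 5 gave 1367 rising and 765 falling genes, E18.5 minus E11.5 gave 671 falling, and leaving out E18.5 gave 1916 falling.

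**Figure D2:**
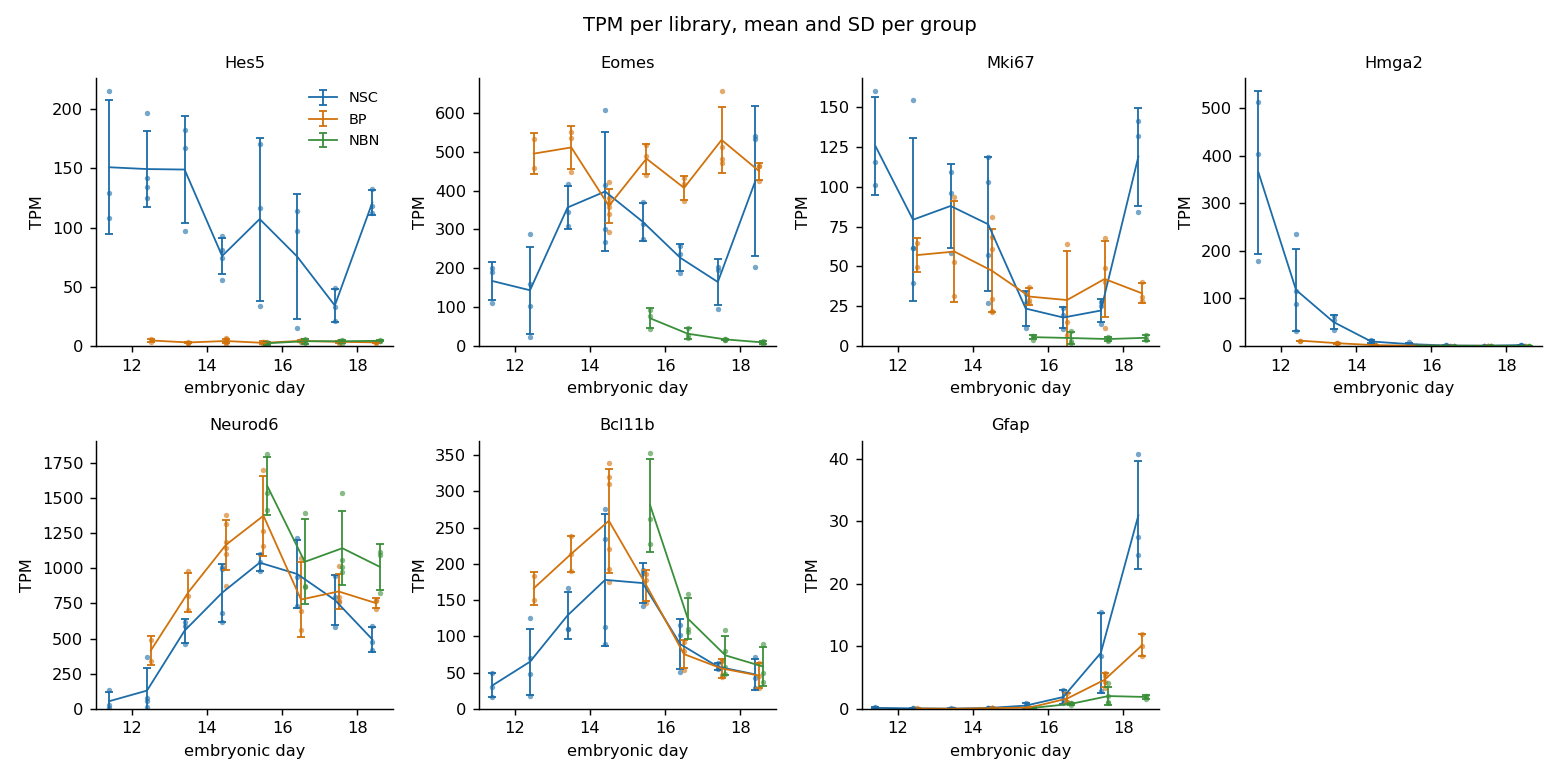
TPM of Hes5, Eomes, Mki67, Hmga2, Neurod6, Bcl11b and Gfap by embryonic day. Points are libraries, and lines join group means with their standard deviations.

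BP were followed from E12.5 to E18.5 (24 libraries). The largest rises are those of 4 adult globins, Hbb-bs (7.06 ± 0.96, adjusted p = 3.2e-08), Hba-a2 (6.35 ± 1.01, adjusted p = 9.02e-07), Hbb-bt (6.20 ± 0.97, adjusted p = 7.37e-07) and Hba-a1 (6.09 ± 1.00, adjusted p = 1.71e-06), and of the tachykinin gene Tac2 (from 0 ± 0 to 35.4 ± 3.83 TPM, 6.07 ± 0.24, adjusted p = 2.27e-25). The 4 globins summed to 1.257 and 0.3676 TPM in the only 2 BP libraries of E12.5. Within BP of E16.5 the sums were 118.1, 206 and 2733 TPM, so globin levels differed widely between libraries of 1 day. Their source was not tested. The largest falls are those of Crabp2 (from 382 ± 153 to 1.89 ± 0.345 TPM, -7.34 ± 0.32, adjusted p = 5.09e-24), the patterning factors Fezf1 (-6.61 ± 0.48, adjusted p = 4.91e-16) and Uncx (-5.27 ± 0.62, adjusted p = 8.75e-10), the axon guidance receptor Robo3 (-6.34 ± 0.28, adjusted p = 1.07e-23) and Ebf2 (-6.19 ± 0.30, adjusted p = 3.45e-22). Of 15231 genes, 1051 rose and 668 fell, a share of 61.1% rising, which is 50.6% with quantile scaling.

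Deep-layer calls in BP are mostly falls and upper-layer calls mostly rises. Deep-layer genes rose in 2 of 14 cases and fell in 7 (adjusted p = 0.00211, and adjusted p = 0.338 with an estimated correlation), with Bcl11b at -2.43 ± 0.37 (adjusted p = 3.25e-07), Tbr1 at -1.99 ± 0.33 and, rising, Crym at 4.86 ± 0.59. Upper-layer genes rose in 10 of 15 and fell in 1 (adjusted p = 4.19e-06, and adjusted p = 0.102 with an estimated correlation), with Ptn at 3.71 ± 0.21 (adjusted p = 6.26e-20). The early temporal progenitor list had 1 of 18 up and 9 down (adjusted p = 4.42e-10, and adjusted p = 0.021 with an estimated correlation), with the RNA-binding genes Igf2bp1 at -2.47 ± 0.19 and Igf2bp2 at -4.06 ± 0.24, and Sfrp2 the gene that rose (1.66 ± 0.25). Astrocyte genes had 17 of 25 up and 0 down (adjusted p = 2.58e-07, and adjusted p = 0.0801 with an estimated correlation), with Gfap at 3.51 ± 0.24 (adjusted p = 6.08e-17), or 2.31 over the days to E17.5. Ependymal genes had 0 of 11 up and 4 down (adjusted p = 3.09e-05, and adjusted p = 0.021 with an estimated correlation), with Foxj1 at -2.0 ± 0.18 and Mcidas at -2.76 ± 0.22, both drivers of multiciliated cells. G2 and M genes had 0 of 22 up and 9 down (adjusted p = 5.58e-07, and adjusted p = 0.338 with an estimated correlation), with Ube2c at -1.28 ± 0.21. Cholesterol genes had 0 of 18 up and 3 down (adjusted p = 4.19e-06, and adjusted p = 0.222 with an estimated correlation).

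Genes of vessel and other cells are called in BP too. Endothelial and pericyte genes had 11 of 14 up and 0 down (adjusted p = 0.0015, and adjusted p = 0.404 with an estimated correlation), with Rgs5 at 2.53 ± 0.29 and Cldn5 at 2.72 ± 0.44. Rgs5 is not called with a pseudocount of 5 (0.999). Erythroid genes had 5 of 10 up and 1 down (adjusted p = 0.25), meninges genes 5 of 13 up and 1 down (6 and 1 over the list alone, adjusted p = 0.333), choroid plexus genes 3 of 9 up and 0 down (adjusted p = 0.333) and immediate early genes 4 of 19 up and 0 down (3 and 0 over the list alone, adjusted p = 0.798). Every other count is the same over the list alone.

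Of the genes followed throughout, Hmga2 fell from 11.5 ± 0.0453 to 0.411 ± 0.0589 TPM (-3.10 ± 0.31, adjusted p = 1.16e-11), and Bcl11b and Gfap changed as given above. Not called were Hes5 (-0.20 ± 0.38), Pax6 (0.97 ± 0.26), Eomes (-0.03 ± 0.36), Neurog2 (-0.12 ± 0.26), Tubb3 (-0.68 ± 0.22), Neurod6 (0.44 ± 0.47), Olig2 (0.37 ± 0.38) and Mki67 (-0.98 ± 0.49). Pax6 is called rising without BP E12.5 replicate 2 (1.08), BP E16.5 replicate 2 (1.02), BP E17.5 replicate 2 (1.04) or E18.5 (1.00), and Mki67 is called falling without BP E16.5 replicate 1 (-1.16). A pseudocount of 0.1 gave 1588 rising genes and a pseudocount of 5 gave 485 rising and 349 falling.

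The courses of NSC and BP overlap. Of 15231 genes, 661 rose in both, where 155.5 would be shared if the calls were independent, and 300 fell in both (54.6). Opposite calls are below that number: 52 genes rose in NSC and fell in BP (98.9) and 15 fell in NSC and rose in BP (85.8). The slopes correlate across genes at r = 0.554, although genes are not independent replicates. Mef2c is among the opposite genes, with slopes of 4.92 in NSC and -1.34 in BP. Carried neurons were not set apart from its rise in NSC. With a pseudocount of 0.1 or 5, 994 or 340 rose in both and 453 or near 1.5e2 fell in both. Then 106 or 21 rose in NSC and fell in BP and 37 or 1 fell in NSC and rose in BP. With NSC slopes over E12.5 to E18.5 the opposite counts are 22 and 4, and with library weights 29 genes rose in NSC and fell in BP.

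NBN were followed from E15.5 to E18.5 (13 libraries). Neurotensin, Nts, rose from 1.84 ± 1.03 to 57.1 ± 12.7 TPM (n = 3 each, 4.66 ± 0.84, adjusted p = 4.34e-05). The next largest rises are microglia and macrophage genes: the complement genes C1qc (4.02 ± 0.55, adjusted p = 2.56e-07), C1qb (3.98 ± 0.56, adjusted p = 4.91e-07) and C1qa (3.88 ± 0.55, adjusted p = 5.77e-07) and the chemokine Pf4 (3.89 ± 0.56, adjusted p = 6.72e-07). Falling most were regulators of G-protein signalling, Rgs16 (from 89.9 ± 13.4 to 4.65 ± 1.37 TPM, -4.01 ± 0.17, adjusted p = 2.85e-23) and Rgs8 (-3.88 ± 0.31, adjusted p = 1.94e-13), the melanocortin receptor Mc4r (-3.80 ± 0.34, adjusted p = 6.94e-12), Zfp521 (-3.44 ± 0.25, adjusted p = 2.65e-14) and Lrrtm3 (-3.11 ± 0.30, adjusted p = 5.51e-11). Of 15231 genes, 502 rose and 220 fell.

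In NBN, deep-layer genes fell in 11 of 14 cases and rose in 2 (adjusted p = 1.78e-13, and adjusted p = 0.00871 with an estimated correlation). They include Sox5 (-2.87 ± 0.35), Tle4 (-2.03 ± 0.26), Nfe2l3 (-2.49 ± 0.32) and Bcl11b (-2.33 ± 0.41, adjusted p = 3.07e-05), and Etv1 rose (1.84 ± 0.57, adjusted p = 0.0189). Etv1 is not called without NBN E15.5 replicates 1 (1.69) or 2 (1.77) or NBN E18.5 replicates 1 (1.78) or 2 (1.68). Upper-layer genes rose in 7 of 15 and fell in 1 (7 and 2 over the list alone, adjusted p = 1.37e-06, and adjusted p = 0.0644 with an estimated correlation), with Lmo4 at 2.23 ± 0.17 (adjusted p = 2.65e-14), and Rorb fell (-1.55 ± 0.32). Basal progenitor genes rose in 0 of 20 and fell in 10 (adjusted p = 2.32e-12, and adjusted p = 0.0644 with an estimated correlation), among them Eomes (-2.72 ± 0.41, adjusted p = 1.57e-06), Neurog1 (-2.87 ± 0.28) and Gadd45g (-1.69 ± 0.22). Cholesterol synthesis genes rose in 6 of 18 and fell in 0 (adjusted p = 8.26e-18, and adjusted p = 0.00871 with an estimated correlation), with Insig1 at 1.06 ± 0.12 and Fdps at 1.33 ± 0.16. Microglia genes rose in 11 of 15 and fell in 0 (adjusted p = 8.76e-16, and adjusted p = 0.0644 with an estimated correlation). Over the days to E17.5, Insig1 (0.84) and Fdps (0.97) are not called, nor is Insig1 with a pseudocount of 5 (0.999).

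Glial and endothelial lists rose in NBN as well. Astrocyte genes had 11 of 25 up and 2 down (12 and 2 over the list alone, adjusted p = 2.96e-06, and adjusted p = 0.0887 with an estimated correlation), with Apoe at 3.41 ± 0.44, and oligodendrocyte genes 5 of 17 up and 0 down (adjusted p = 0.00148, and adjusted p = 0.269 with an estimated correlation), with Olig1 at 3.75 ± 0.40. Endothelial and pericyte genes had 3 of 14 up and 0 down (adjusted p = 0.00485, and adjusted p = 0.682 with an estimated correlation). Early temporal progenitor genes had 0 of 18 up and 3 down (adjusted p = 0.000104, and adjusted p = 0.134 with an estimated correlation). Immediate early genes had 2 of 19 up and 0 down (5 and 0 over the list alone, adjusted p = 0.23). All other counts are the same over the list alone. Among the genes named in every comparison, Olig2 (2.49 ± 0.43, adjusted p = 2.02e-05) and Gfap (1.39 ± 0.27, adjusted p = 0.000124) rose and Neurog2 fell (-1.50 ± 0.28, adjusted p = 9.48e-05), and not called were Hes5 (0.69 ± 0.43), Pax6 (-0.57 ± 0.29), Tubb3 (0.31 ± 0.24), Neurod6 (-0.55 ± 0.52), Hmga2 (-0.30 ± 0.35) and Mki67 (-0.09 ± 0.55). A pseudocount of 0.1 gave 775 rising genes and a pseudocount of 5 gave 184 rising and 132 falling. With the latter Gfap is 0.46 and not called. A mean of at least 5 TPM left 223 rising and leaving out E18.5 left 265.

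**Figure D3:**
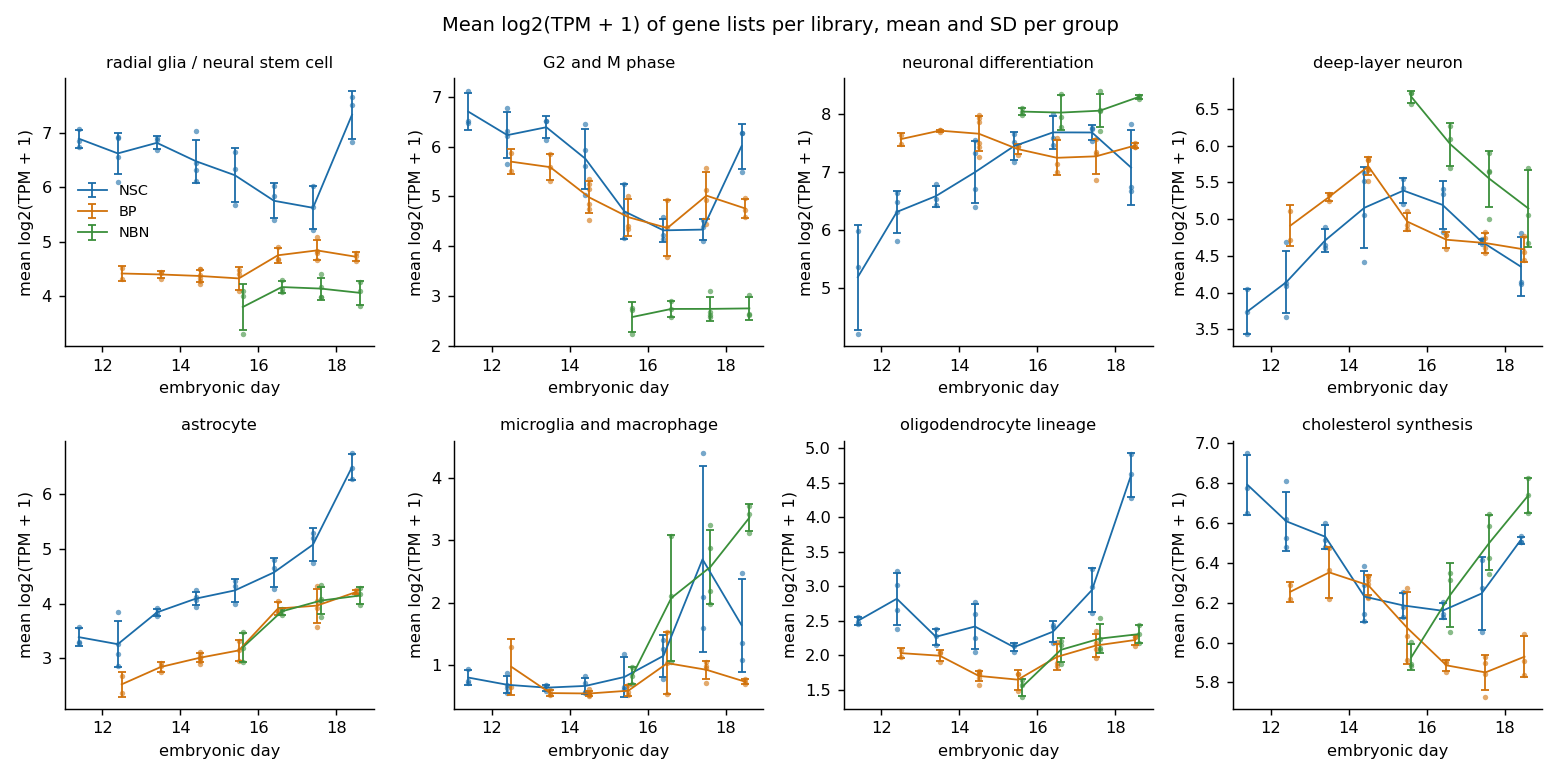
Mean log2(TPM + 1) of 8 gene lists per library by embryonic day. Lines join group means with their standard deviations.

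Slopes differ between NSC and BP (23 and 24 libraries, E12.5 to E18.5). For neuron genes and lists the NSC slope may hold a part from carried neurons, which was not tested. The slope of Mef2c was 5.50 ± 0.59 (adjusted p = 1.34e-09) higher in NSC, that of the synaptic adhesion gene Lrfn5 4.65 ± 0.54 (adjusted p = 7.38e-09) and that of Tnc 4.58 ± 0.44 (adjusted p = 5.96e-11) (3.03 over the days to E17.5). Slopes were lower in NSC for the Wnt effector Tcf7l2 (-3.44 ± 0.86, adjusted p = 0.00199), the kinase Ak4 (-3.30 ± 0.29, adjusted p = 4.39e-12) and Hbb-y (-3.22 ± 1.22, adjusted p = 0.0398). Without NSC of E12.5, Tcf7l2 is -0.85 and Hbb-y 0.56, neither called, and Hbb-y is not called without any 1 of 14 libraries (-3.27 to -2.24, the latter without NSC E12.5 replicate 4) or NSC of E17.5 (-3.57). Nor is it called with a pseudocount of 0.1 (-4.06), no low-value filter or the libraries of the contrast alone (-3.22 each). The call of Hbb-y also ends with the transcript length covariate (-2.05) or far libraries left out (-2.99). In all, 1045 genes had a higher slope in NSC and 558 a lower one.

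Neuronal differentiation genes had a higher slope in NSC in 15 of 24 cases and a lower one in 0 (16 and 0 over the list alone, adjusted p = 5.72e-07, and adjusted p = 0.356 with an estimated correlation), and synapse genes in 8 of 20 with 0 lower (9 and 0, adjusted p = 3.14e-07, and adjusted p = 0.235 with an estimated correlation). Oligodendrocyte genes had 9 of 17 higher and 1 lower (adjusted p = 2.05e-05, and adjusted p = 0.225 with an estimated correlation), with Gpr17 at 2.85 ± 0.24. Astrocyte genes had 9 of 25 higher and 2 lower (10 and 2, adjusted p = 3.37e-05, and adjusted p = 0.225 with an estimated correlation), with Hepacam at 2.95 ± 0.25. Over the days to E17.5 Gpr17 is 0.79, not called, and Hepacam 1.38. Microglia genes had 10 of 15 higher and 0 lower (adjusted p = 4.76e-05, and adjusted p = 0.462 with an estimated correlation) and ependymal genes 5 of 11 higher and 0 lower (adjusted p = 0.000325, and adjusted p = 0.147 with an estimated correlation). S phase genes had 0 of 22 higher and 14 lower (adjusted p = 1.03e-13, and adjusted p = 0.225 with an estimated correlation), with Ung at -2.45 ± 0.33 and Mcm6 at -1.81 ± 0.24, and radial glia genes 0 of 22 higher and 10 lower (adjusted p = 0.00264, and adjusted p = 0.584 with an estimated correlation), with Sox2 at -2.0 ± 0.32. For the last minus the first day Mcm6 (-0.90, adjusted p = 0.0637) and Sox2 (-1.11, adjusted p = 0.0803) are not called. Over the list alone, interneuron genes go from 1 and 1 to 1 and 0, erythroid genes from 0 and 2 to 0 and 0 and immediate early genes from 1 and 0 to 0 and 0, the other counts being the same.

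Among the genes named in every comparison, slopes were higher in NSC for Bcl11b (1.61 ± 0.49, adjusted p = 0.011), Gfap (1.20 ± 0.32, adjusted p = 0.00381) and Olig2 (1.32 ± 0.52, adjusted p = 0.0473) and lower for Pax6 (-1.92 ± 0.35, adjusted p = 4.24e-05) and Hmga2 (-2.60 ± 0.42, adjusted p = 5.98e-06). Not called were Hes5 (-0.97 ± 0.52), Eomes (0.60 ± 0.49), Neurog2 (-0.67 ± 0.34), Tubb3 (0.89 ± 0.29), Neurod6 (1.59 ± 0.63) and Mki67 (0.21 ± 0.66). Olig2 is called by little: it is lost without any 1 of 26 of 41 libraries (0.97 to 1.38, lowest without NSC E12.5 replicate 3), is 2.25 without NSC of E12.5 and turns to -0.57 without E18.5. Gfap is lost without NSC E17.5 replicate 1 (0.995) or E18.5 (0.48) and Bcl11b without NSC of E12.5 (0.89), and Pax6 is -1.27 without NSC of E17.5. For the last minus the first day, Pax6 (-0.66, adjusted p = 0.403), Bcl11b (1.68, adjusted p = 0.0921) and Olig2 (1.84, adjusted p = 0.0729) are not called and Eomes is (2.05), as it is with library weights (1.01). Bcl11b is also lost with the transcript length covariate (0.89), where Tubb3 is called (1.03). Gfap is also lost with a pseudocount of 0.1 (1.06) or 5 (0.97) or library weights (0.93). Calls appear without E18.5 for Hes5 (-1.96), Tubb3 (1.57) and Neurod6 (2.11), without NSC of E12.5 for Neurog2 (-1.23), without NSC E18.5 replicate 3 for Tubb3 (1.01) and without any 1 of 8 libraries for Neurod6 (1.61 to 2.10, highest without NSC E12.5 replicate 3). Higher slopes numbered 540 with a pseudocount of 5, 657 at a mean of at least 5 TPM and 563 for the last minus the first day. Lower slopes numbered 253 with a pseudocount of 5, 196 for the last minus the first day, 1221 without E18.5, 371 without NSC of E17.5 and 368 without NSC of E12.5.

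Between NBN and BP (13 libraries each, E15.5 to E18.5), the slope was higher in NBN for Nts (6.45 ± 1.19, adjusted p = 0.0003), C1qc (3.95 ± 0.78, adjusted p = 0.000879) and C1qa (3.81 ± 0.78, adjusted p = 0.00136), and over the days to E17.5 Nts (3.17) and C1qa (2.68) are not called. Nor is C1qa with a pseudocount of 0.1 (4.46). It was lower for the chromatin factor Dpf3 (-3.68 ± 0.53, adjusted p = 6.54e-06), Rgs6 (-3.36 ± 0.47, adjusted p = 3.99e-06) and Stac2 (-3.24 ± 0.47, adjusted p = 7.21e-06). In all, 156 genes had a higher slope in NBN and 210 a lower one, a share of 42.6% higher, which is 60.9% with quantile scaling and 56.4% with median-of-ratios scaling.

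Cholesterol synthesis genes had a higher slope in NBN in 10 of 18 cases and a lower one in 0 (adjusted p = 3.36e-39, and adjusted p = 2.32e-05 with an estimated correlation), with Insig1 at 1.25 ± 0.18 (adjusted p = 4.09e-06), the enzyme gene Mvd at 1.46 ± 0.21 (adjusted p = 4.09e-06) and Fdps at 1.48 ± 0.23 (adjusted p = 1.65e-05). Microglia genes had 11 of 15 higher and 0 lower (13 and 0 over the list alone, adjusted p = 4.93e-25, and adjusted p = 0.0203 with an estimated correlation), with Mrc1 at 3.36 ± 0.53 (1.95 over the days to E17.5). Deep-layer genes had 0 of 14 higher and 5 lower (1 and 8, adjusted p = 2.98e-06, and adjusted p = 0.167 with an estimated correlation), with Tle4 at -2.15 ± 0.36 (-1.41 over the days to E17.5). Basal progenitor genes had 1 of 20 higher and 6 lower (adjusted p = 0.00418, and adjusted p = 0.824 with an estimated correlation). Over the list alone there are also other counts: neuronal differentiation 3 higher (2 over all genes), synapse 2 and 1 (1 and 1), Notch 3 (1), Wnt 2 lower (1), astrocyte 1 and 4 (0 and 1) and Cajal-Retzius 1 lower (0).

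Among the genes named in every comparison, the slope was lower in NBN for Eomes (-2.74 ± 0.57, adjusted p = 0.00175), Neurog2 (-1.57 ± 0.40, adjusted p = 0.0147) and Gfap (-1.85 ± 0.38, adjusted p = 0.00135). Neurog2 is not called without NBN E15.5 replicate 1 (-1.46) or 3 (-1.36), nor without E18.5 are Eomes (-2.06) and Gfap (-0.94). Not called were Hes5 (0.57 ± 0.60), Pax6 (-0.86 ± 0.41), Tubb3 (0.47 ± 0.34), Neurod6 (0.17 ± 0.74), Bcl11b (-0.46 ± 0.58), Hmga2 (0.16 ± 0.49), Olig2 (1.06 ± 0.60) and Mki67 (-0.41 ± 0.77). Olig2 is called with the libraries of the contrast alone (adjusted p = 0.0459). Higher slopes numbered 95 with a pseudocount of 5, 61 at a mean of at least 5 TPM, 246 with library weights and 35 without E18.5. Lower slopes numbered 128 with a pseudocount of 5, 417 with library weights and 117 without E18.5.

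In NSC some genes bend in mid-course (26 libraries, 8 days). High and low here compare the middle of a fit with the mean of its ends. The highest or lowest level of a gene may still lie at an end. Against the ends of a quadratic fit, the middle was higher for Ndrg1 (3.49 ± 0.32, adjusted p = 2.02e-12), the guanine exchange factor Tiam2 (3.30 ± 0.26, adjusted p = 2.96e-14) and the cadherin Cdh13 (3.21 ± 0.28, adjusted p = 1.12e-12). It was lower for Olig2 (16.4 ± 5.02, 2.54 ± 0.473 and 101 ± 40.1 TPM at E11.5, E15.5 and E18.5, -3.12 ± 0.30, adjusted p = 8.05e-12), Olig1 (-3.05 ± 0.28, adjusted p = 1.75e-12) and Otx2 (-2.66 ± 0.49, adjusted p = 1.38e-05). Over the days to E17.5 Ndrg1 is 1.60, Cdh13 2.13, Olig2 -1.50 and Olig1 -1.76. In all, 476 genes were higher in mid-course and 758 lower, a share of 38.6% higher, which is 58.7% with quantile scaling and 51.8% with median-of-ratios scaling.

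Neuronal lists were high in mid-course. Deep-layer genes had 10 of 14 high and 1 low (adjusted p = 1.36e-06, and adjusted p = 0.149 with an estimated correlation), with Nxph3 at 2.79 ± 0.25 and Rprm at 1.96 ± 0.21, and neuronal differentiation genes 9 of 24 high and 0 low (adjusted p = 6.55e-09, and adjusted p = 0.288 with an estimated correlation), with Bhlhe22 at 2.26 ± 0.22 and Neurod2 at 2.72 ± 0.30. Basal progenitor genes had 6 of 20 high and 0 low (adjusted p = 0.000234, and adjusted p = 0.322 with an estimated correlation). Oligodendrocyte genes had 0 of 17 high and 9 low (adjusted p = 2.91e-08, and adjusted p = 0.0948 with an estimated correlation). Astrocyte genes had 3 of 25 high and 12 low (adjusted p = 0.000703, and adjusted p = 0.288 with an estimated correlation), with Aqp4 at -1.54 ± 0.11 (not called at -0.30 without E18.5 and -0.80 with a pseudocount of 5). The mean of the astrocyte list rose from 3.26 ± 0.42 at E12.5 through 4.24 ± 0.22 at E15.5 to 6.50 ± 0.24 at E18.5. G2 and M genes had 0 of 22 high and 13 low (adjusted p = 1.56e-06, and adjusted p = 0.336 with an estimated correlation), S phase genes 0 of 22 high and 9 low (adjusted p = 5.38e-08, and adjusted p = 0.288 with an estimated correlation), and radial glia genes 0 of 22 high and 7 low (adjusted p = 0.000205, and adjusted p = 0.366 with an estimated correlation). Over the list alone erythroid genes go from 0 high and 2 low to 0 and 0 and all other counts are the same.

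Among the genes named in every comparison, Neurod6 (3.11 ± 0.36, adjusted p = 1.58e-09), Bcl11b (2.15 ± 0.28, adjusted p = 2.68e-08) and Neurog2 (1.06 ± 0.20, adjusted p = 1.8e-05) were high in mid-course. Gfap (-2.27 ± 0.19, adjusted p = 1.09e-13), Hmga2 (-2.12 ± 0.24, adjusted p = 8.2e-10) and Mki67 (-1.66 ± 0.38, adjusted p = 0.000307) were low against the ends of the fit. Over the whole course Gfap rose and Hmga2 fell, as given above. Not called were Hes5 (-0.61 ± 0.30), Pax6 (-0.73 ± 0.20), Eomes (0.56 ± 0.28) and Tubb3 (0.69 ± 0.17). Over the days to E17.5 Gfap is -1.48, Hmga2 (-0.96) and Mki67 (-0.02) are not called, and Eomes is called (1.22). Neurog2 is not called with library weights (0.71). Nor is it without NSC of E17.5 (0.995) or without 1 of NSC E11.5 replicate 1 (0.97), NSC E14.5 replicate 1 (0.99), NSC E15.5 replicate 1 (0.98) and NSC E18.5 replicate 1 (0.86). High genes numbered 737 with a pseudocount of 0.1, 263 with a pseudocount of 5 and 293 without E18.5. Low genes numbered 1455, 224 and 211 in the same order, 411 at a mean of at least 5 TPM and 431 with quantile scaling.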

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

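The tests of neuron transcript shares, of transcript length and GC content, and of the gap between the microglia and other lists were chosen only after the result was seen.

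In 9 of 90 tests of a gene in a group of at least 4 libraries, a library lay far from the others, where chance gives this in about 1 in 20 groups. In 4 of the 9 the gene is Xist or the Y-linked Kdm5d and the library is the 1 of its group without Y-linked transcripts, so the mix of sexes sets the outcome and these 4 do not point to an unusual library. Ski had 22.4 TPM in BP E14.5 replicate 6 (others 27 to 29.1), Pax6 31.6 in NBN E17.5 replicate 4 (13.1 to 14) and Hmga2 1.03 in BP E17.5 replicate 4 (0.486 to 0.556). Neurod6 had 1020 TPM in BP E17.5 replicate 1 (760 to 797) and 1540 in NBN E17.5 replicate 1 (972 to 1060). Xist had 262 TPM in NSC E14.5 replicate 3 (0.159 to 16), 223 in BP E17.5 replicate 1 (0.119 to 4.47) and 234 in NBN E17.5 replicate 1 (0.0654 to 0.249), and the Y-linked Kdm5d had 0.0554 in the last of these libraries (9.44 to 11.3).

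Slopes on day differ between NSC and BP by a test of the difference, with 1045 genes higher and 558 lower in NSC. Higher are Mef2c (5.50), Lrfn5 (4.65), Tnc (4.58), Hepacam (2.95), Gpr17 (2.85), Bcl11b (1.61), Olig2 (1.32) and Gfap (1.20). Lower are Tcf7l2 (-3.44), Ak4 (-3.30), Hbb-y (-3.22), Hmga2 (-2.60), Ung (-2.45), Sox2 (-2.0), Pax6 (-1.92) and Mcm6 (-1.81). Some of these rest on few days: without NSC of E12.5 Tcf7l2 is -0.85 and Hbb-y 0.56, and without E18.5 Olig2 is -0.57, Gpr17 0.79 and Gfap 0.48, none of them called. The call of Hbb-y also ends without any 1 of 14 libraries. Of 100 splits of the libraries 3, the real one included, gave as many called genes, and the highest other split, with 2172 called genes, lies above the real 1603. These splits shuffled cell type within each day, so they test whether NSC and BP libraries can be exchanged. They cannot decide whether chance gives the difference in slopes.

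Slopes also differ between NBN and BP by a test of the difference, with 156 genes higher and 210 lower in NBN. With median-of-ratios scaling the balance turns, with 190 higher and 147 lower. Higher are Nts (6.45), C1qc (3.95), C1qa (3.81), Mrc1 (3.36), Fdps (1.48), Mvd (1.46) and Insig1 (1.25). Lower are Dpf3 (-3.68), Rgs6 (-3.36), Stac2 (-3.24), Eomes (-2.74), Tle4 (-2.15), Gfap (-1.85) and Neurog2 (-1.57). Without E18.5 Nts (3.17), C1qa (2.68), Eomes (-2.06) and Gfap (-0.94) are not called. Here too 3 of 100 splits gave as many called genes as the real 366, and the highest other split, with 2917, lies above it. As cell type was shuffled within each day, these splits cannot decide here either whether chance gives the difference in slopes. A shuffle that exchanges cell types more on 1 day than on another puts the difference between NBN and BP, with 1652 called genes, into the slope contrast. A split above the real number can therefore come from the shuffling itself.

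For the other 7 comparisons 1 of 100 splits, the real one, gave as many called genes. For the cell type comparisons and the slopes within 1 cell type, no shuffled split reached the real number. The splits take libraries as independent, which the labels do not say, so they cannot exclude chance. For the bend, the shuffled days test any change with day, so the splits cannot single out a bend. The real and highest other numbers are 461 and 35 for NSC against BP, 1652 and 833 for NBN against BP and 1318 and 565 for NBN against NSC. They are 3498 and 1453 for the NSC slope, 1719 and 832 for the BP slope, 722 and 164 for the NBN slope and 1234 and 1204 for the bend in mid-course.

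Neuron transcripts are high in mid-course in NSC libraries, although no list passes for the bend with an estimated correlation. Neurons carried in the NSC sort may be a source: over 28 abundant neuron genes the E15.5 level above that of E11.5 and E12.5 was a median of 38.2% of the NBN level, with a ratio of upper to lower quartile of 2.48, within the 3-fold set for a shared source, and 1 of the 28 genes above 100%. The median share was 55.3% at E16.5, with 2 of 25 genes above 100% (highest 183%), 65.3% at E17.5, with 3 of 27 (highest 154%), and 31.3% at E18.5, with 1 of 31 and a range from -16.4% to 111%. At E15.5 the range was 14.6% to 108%. Shares above 100% or below 0% are not what carried neurons alone would give if they had the NBN levels of that day. That premise, and an E11.5 and E12.5 level free of neurons, were not tested. Carried neurons would bear on the NSC slope and on comparisons of NSC with BP or NBN too, where they were not set apart. The number of genes high in mid-course did not shrink with median-of-ratios scaling (591, against 476). It counts all tested genes and not the neuron transcripts alone. It therefore cannot decide whether scaling of TPM to a fixed total is a source for them. A lower share of dividing cells stays open: within groups the G2 and M list and the neuron lists correlate at r = -0.364 over 26 NSC libraries (p = 0.171), and neuronal transcription by Hes5::GFP cells was not tested.

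The first axis of variation within groups holds 29.4% of that variance. Bias between libraries by transcript content is a candidate explanation, as its loadings correlate across genes with GC content (rho = 0.57) and transcript length (rho = -0.314), with 98.6% of tested genes matched. Embryos of 1 day at different stages stay open, as the loadings correlate with the BP slope at r = 0.182 and the NSC slope at r = 0.077. The loadings correlate more with the bend of NSC (r = 0.289), the NBN slope (0.275) and the NSC minus BP slope (-0.222). Genes are not independent replicates in these values, and what the axis is remains unsettled.

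Microglia genes rise in NBN libraries, although the list does not pass for the NBN slope with an estimated correlation. Microglia carried in the NBN sort may be the source: within groups the 15 genes correlate at a mean pairwise r of 0.796 over 13 libraries, against a median of 0.063 and an upper bound of 0.21 in 1000 random lists of matched level. A lower share of neurons would raise markers of every other cell type alike. The mean slope of the list exceeds the highest of 4 other lists (endothelial, erythroid, meninges and choroid plexus) by 1.67. This argues against such a share as the only source for those 4 lists, some of which lie near the floor. The astrocyte and oligodendrocyte lists, which also rose in NBN, were not part of that comparison. No biological explanation was tested, and how many such cells the libraries hold is not given by these values.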

How the results depend on the processing

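The alternatives that leave out E18.5, NSC of E17.5, NSC of E12.5 or far libraries, that keep E12.5 to E14.5, that add the transcript length covariate or that test lists without NSC E17.5 replicate 1 were chosen only after the results were seen. Of 339 values of counts and lists under other settings 267 stayed within 1.5 times the main value, as did 502 of 502 counts with 1 library left out. The 72 that moved, and 4 named values whose direction turned with a call in at least 1 of the fits, follow by setting. The cause was not tested. Of 3939 values of named genes under other settings 3830 kept their call or lack of one, 73 lost and 32 gained a call. With 1 library left out these are 7437 of 7511, 59 and 15. A value that turned direction but is called in neither fit counts as kept.

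With a pseudocount of 0.1, NSC against BP gave 740 and 157 genes, NBN against BP 1317 up, NBN against NSC 731 and 1419, the BP slope 1588 rising, the NBN slope 775 rising and the bend 737 high and 1455 low. NSC and BP slopes then shared 994 rising and 453 falling genes, with 106 and 37 opposite. With a pseudocount of 5 the counts were 170 and 25, 470 and 400, 149 and 456, 1367 and 765 (NSC slope), 485 and 349 (BP), 184 and 132 (NBN), 540 and 253 (NSC minus BP), 95 and 128 (NBN minus BP) and 263 and 224 (bend). Shared were then 340 rising and near 1.5e2 falling, with 21 and 1 opposite.

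A mean of at least 5 TPM, which tests fewer genes, gave 223 rising in NBN, 657 with a higher slope in NSC than BP, 61 higher and near 1.4e2 lower slopes for NBN minus BP and 411 low in mid-course. Quantile scaling gave near 1.4e2 lower slopes in NBN and 431 low in mid-course. Library weights gave 246 and 417 for NBN minus BP and 29 genes rising in NSC and falling in BP. The last minus the first day gave 671 falling in NSC and 563 and 196 for NSC minus BP. NSC slopes over E12.5 to E18.5 gave 22 and 4 opposite genes.

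With a pseudocount of 0.1 Gfap in NBN against BP (-1.19) gains a call. Library weights add Mki67 in the BP slope (-1.10). Olig2 in NSC minus BP is also lost with a pseudocount of 0.1 (1.23) or library weights (0.93), and with no low-value filter or the libraries of the contrast alone (1.32 each), and Neurod6 there is called with 6 planned settings that have no block (1.52 to 1.71).

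Without E18.5 there were 252 genes higher in NBN than NSC, 1916 falling in NSC, 265 rising in NBN, 1221 lower slopes in NSC than BP, 35 and 117 for NBN minus BP and 293 high and 211 low in mid-course. Olig2 turned in the NSC slope (-1.17) and in NSC minus BP (-0.57). Only E12.5 to E14.5 gave 681 and 243 genes for NSC against BP, and Mef2c turned (-1.24). Lower slopes in NSC than BP numbered 371 without NSC of E17.5 and 368 without NSC of E12.5, where Hbb-y turned (0.56).

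With an estimated correlation between genes the lists passing, out of 28, were 3 of 17 for NSC against BP, 0 of 10 for NBN against BP and 0 of 17 for NBN against NSC. They were 1 of 17, 2 of 13 and 2 of 10 for the slopes of NSC, BP and NBN, 0 of 13 and 2 of 10 for NSC minus BP and NBN minus BP, and 0 of 14 for the bend. Quantile scaling lost synapse in NSC against BP, radial glia and basal progenitor in the NSC slope, Wnt response in the BP slope, SKI partners in the NBN slope and immediate early and hypoxia in NBN minus BP. Without NSC E17.5 replicate 1, 17 of 28 lists pass for the NSC slope.

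Replicate numbers were taken to pair the samples if every pair correlates above 0.1 in its deviations, which BP and NBN miss by 1 pair: 12 of 13 BP and NBN pairs of 1 number and day do so (lowest -0.149), and 11 of 13 correlate best with their own number, as against 7 of 21 pairs above 0.1 for NSC and BP and 6 of 12 for NSC and NBN. Sex transcripts match in 13 of 13 BP and NBN pairs, a hint from the data and not the design. A replicate block gave 360 lower slopes in NBN than BP, the 1 count it moved by more than 1.5 times, and named genes that changed call under it are Eomes in NSC against BP (-1.02), Olig2 (0.94), Hbb-y (-2.07) and Neurod6 (2.36) in NSC minus BP and Olig2 in NBN minus BP (1.06). Of the lists passing, the block lost radial glia in NBN against BP and early neuroepithelium in NSC minus BP. Depth could not be varied, since TPM keep no read counts.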

Other observations

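This part gives values and no tests, and the items in it were chosen after their values were seen. Lists in NSC take different courses to E18.5. The mean log2(TPM + 1) of S phase genes was 7.09 ± 0.14 at E11.5, 4.94 ± 0.08 at E17.5 and 5.93 ± 0.48 at E18.5 (n = 3 each). That of astrocyte genes was 3.38 ± 0.16, 5.08 ± 0.30 and 6.50 ± 0.24, and that of upper-layer genes 4.12 ± 0.32, 6.37 ± 0.31 and 6.32 ± 0.16. In NBN the G2 and M list was 2.58 ± 0.29 at E15.5 and 2.75 ± 0.23 at E18.5.

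Of the 52 genes that rose in NSC and fell in BP, a number that is 22 with NSC slopes over E12.5 to E18.5, Glra2, a glycine receptor subunit, had 2.11 in NSC and -1.57 in BP, Grm2, a metabotropic glutamate receptor, 2.12 and -1.35, and the neuronal translation factor Eef1a2 2.39 and -1.08. The kinase Plk2 had 1.84 and -1.66 and the co-repressor Runx1t1 1.04 and -2.75. Among the 15 genes with the opposite pattern, the homeobox gene Prrx1 fell in NSC (-1.39) and rose in BP (1.11).

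Microglia genes had a mean log2(TPM + 1) of 0.83 ± 0.14 in NBN of E15.5, 2.08 ± 1.02 at E16.5, 2.57 ± 0.60 at E17.5 and 3.36 ± 0.22 at E18.5. In NSC the highest value was 2.70 ± 1.49 at E17.5, and in BP 1.03 ± 0.49 at E16.5. Erythroid genes varied most between NSC libraries of E12.5 (3.44 ± 2.58, n = 4) and E17.5 (3.66 ± 1.84, n = 3).

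Ski had 37.38 TPM in BP E13.5 replicate 2 and 18.09 and 17.21 in replicates 1 and 3. On the first axis of variation within groups, 8 libraries lie beyond 1.5 standard deviations: NSC E14.5 replicate 2, NSC E16.5 replicate 1, BP E14.5 replicates 1 and 2, BP E16.5 replicate 1, BP E17.5 replicates 2 and 4 and NBN E16.5 replicate 1.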
